A study of Rattus norvegicus with 8 samples.

How the data were processed

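Gene expression was measured in the frontal cortex of male Sprague-Dawley rats, an outbred laboratory strain, on an Affymetrix rat array of short oligonucleotide probe sets. Per the labels, rats of about 200 g were assigned at random to olanzapine at 2 mg/kg/day by intraperitoneal injection or to saline, 20 animals in each group, for 21 days. Arrays were made from 4 animals of each group, numbered 14, 15, 17 and 19 in the saline group and 9, 14, 18 and 19 in the olanzapine group, and each array is named below by its group and animal number. Each array stood for a separate animal, so the spread between arrays of a group holds both animal and technical variation.

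The values deposited by the authors are linear probe set intensities, one table of 31099 probe sets on 8 arrays, of which 57 are control probe sets. All values were above 0. The mean after removing the lowest and highest 2% of values was 500.1 to 500.2 on every array, so the deposited intensities had been scaled to a common trimmed mean. The software, the background correction, the summary of probes into probe sets and the detection calls are not given in the sources used here. Scaling by 1 factor per array leaves any curvature between intensity and RNA amount in place, and differences between arrays that vary with brightness therefore remain in the values.

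Probe sets were named from the platform's 2016 annotation, with symbols updated by Entrez identifier from a RefSeq gene table of the GRCr8 assembly, which was used for names only. Of the 31042 probe sets that were not controls, 20826 had 1 gene symbol, 436 had several and 9780 had none. Only probe sets with 1 symbol were named. Coordinates were not used here.

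Intensities were converted to log2(intensity + 63.5), the added value being the 25th percentile of all deposited values. A log2 difference on this scale understates the change of dim genes. Deposited scaling was kept, because the trimmed means of the arrays agreed. Probe sets whose mean log2 value over the 8 arrays was at or below the 40th percentile were removed, leaving 18625, of which 13104 had 1 symbol and stood for 10123 genes. Olanzapine was compared with saline by a linear model per probe set in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with a two-sided test, no covariates and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values for single genes below come from this limma model. The model was tested on simulated data with the 18625 probe sets' own means and their spreads as moderated by eBayes. This was done 10 times with 200 changed probe sets each, with changes of 1.5-fold to 4-fold set on the log2 scale above. Of 1.5-fold changes 39.6% were called, of 2-fold 85% and of 3-fold 99.2%, and 6.36% of the calls were false. The simulated noise was independent between probe sets and the changes were set by choice, so recovery on the measured arrays may be lower.

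Lists of genes for receptors, pathways and cell types were tested with limma's camera at a preset correlation of 0.01, on 1 probe set per gene, the one with the highest mean, and Benjamini-Hochberg adjustment over the 24 lists with at least 3 members left by the filter. The choroid plexus list had too few members and was not tested. Members called measured below are those left by the filter, and dimmer members on the array are not counted. Camera compares a list with all other genes. With an estimated correlation between members, camera called 0 lists, and fry, which tests whether a list's genes move on balance one way, also called 0, so no call below holds in either of these tests. Where the preset correlation gave a call, the adjusted p with the estimated correlation is printed beside it. For lists called only in an alternative it was computed in that alternative, after the calls had been seen. In simulated data a shift of 0.5 in 10 genes of 1 list was called in 10 of 10 runs, and 0 of 240 tests of lists without a shift were called. Those data held no correlation between genes, and in the measured arrays the other splits into 4 and 4 gave a median of 3 called lists. The mean of each list per array was also compared by an exact two-sided permutation test over the 70 assignments of the 8 arrays, whose smallest possible p is 0.0286. Each list's median difference was set against 10000 random lists of the same size matched on mean expression.

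The lists, the filter, the rule for naming genes and the tests were fixed before the data were examined, except for those tests and alternatives named as chosen later. Since no probe set passed the adjustment, the rule took, in each direction, the 12 genes with the smallest unadjusted p among probe sets whose 4 values in one group all lay above the 4 in the other, then the 3 members of each list with the smallest p, and Reln, Homer1, Rgs2, Gsk3b, Htr2a and Gad1 whatever their p. Other list members were named after their values were seen. Values given for a gene are those of 1 probe set, and other tested probe sets of some genes went the other way. The same sign was found in 3 of 4 for Homer1, 2 of 3 each for Slc1a3, Sv2b and Nsf, and 2 of 4 for Scd2. It was found in 1 of 2 for Pgk1 and 1 of 3 for Shank1. The dopamine receptor gene Drd2 was removed by the filter on dim probe sets. Alternatives covered the scaling between arrays, the added value, the filter, the variance model, array weights, a threshold of 0.1, the animal number as a block, leaving out each array and other list tests. Cyclic loess scaling and the comparison of saline 19 alone against olanzapine were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision: the median standard error of a log2 difference was 0.17.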

Results

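The data are 8 arrays of frontal cortex RNA, 4 from rats given olanzapine, an antipsychotic that blocks serotonin and dopamine receptors, and 4 from rats given saline, after 21 days. The question posed by this design is which transcripts of the frontal cortex differ after repeated olanzapine. Median intensities were 159 to 191 per array, and the median correlation of an array with the others ran from 0.953 in saline 15 to 0.970 in olanzapine 18.

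No single gene passed the adjusted test between olanzapine and saline. The gene with the largest positive difference among those named was Igf2, which encodes insulin-like growth factor 2, with an intensity of 122 ± 48.4 in saline and 359 ± 185 in olanzapine (mean ± SD, n = 4 each). The immediate early transcription factor gene Nr4a1 was at 209 ± 75.3 in saline and 471 ± 65.0 in olanzapine, 2.02-fold on the log2(intensity + 63.5) scale. The gene with the largest negative difference among those named was Mis18a, whose product helps to load centromeric histone, at 474 ± 141 in saline and 178 ± 37.2 in olanzapine. As a group, transcripts typical of the meninges, the membranes around the brain, were higher in olanzapine in all 10 measured members, with a median log2 difference of 0.49.

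By limma, 0 of 18625 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.317. A plain two-sample test without moderation also gave 0. At an unadjusted p under 0.05 there were 1549 probe sets, 854 higher and 695 lower in olanzapine, where 931 are expected on average by chance. Other splits of the arrays into 4 and 4 gave a median of 795.5 such probe sets and up to 1820. Higher probe sets made up 55.1% of the 1549, and 38.4% after median centring of the arrays. With a difference of at least 1.5-fold as well, 227 probe sets remained, 190 higher and 37 lower. Higher ones made up 83.7% of the 227, against 67.0% of 194 after quantile normalization and 65.8% of 202 after median centring. The 4 values of one group all lay above those of the other for 832 probe sets, where chance gives 532 on average at 2.86%. This count was not set against the other splits. Without saline 19, 107 probe sets passed the adjusted test, 11 higher and 96 lower, and 92 of them were among the brightest 5% of probe sets. These 107 include 12 of the 24 genes named below, 2 of the higher ones, Kdm4c and Gtf2a2, and 10 of the lower ones, all but Pdlim7 and Dock3.

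The 12 genes named as higher in olanzapine had log2 differences of 0.37 to 1.14 and none passed with all 8 arrays. Kdm4c, a histone demethylase gene, differed by 0.75 (SE 0.12, limma adjusted p 0.317). Txnip, which encodes the thioredoxin-interacting protein and responds to glucose, differed by 0.60 (SE 0.13). Tmem64 differed by 1.03 (SE 0.23) and Col1a1, a fibrillar collagen gene, by 0.57 (SE 0.14). The remaining ones were Gtf2a2 of the basal transcription machinery, the cytoskeletal linker Epb41l3, Myof, Heg1, the polymerase subunit gene Rev3l and the kinase gene Wnk1. Only 1 of 2 tested probe sets was higher for Epb41l3, and 3 of 4 for Wnk1.

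The 12 genes named as lower in olanzapine had log2 differences of -1.12 to -0.34 and none passed with all 8 arrays. Of these, 8 lay among the brightest 5% of probe sets: Rtn1, Glul, Gnb1, Pkia, Cpe, Snap25, Sptbn1 and Gosr1. Snap25, which encodes a synaptic vesicle fusion protein, had an intensity of 21079 ± 1912 in saline and 16440 ± 1010 in olanzapine (mean ± SD, n = 4 each). Glul, the glutamine synthetase gene of astrocytes, was at 12459 ± 872 in saline and 9484 ± 921 in olanzapine. Only 1 of 2 tested probe sets was lower for Glul and for Pkia, and 2 of 3 for Gnb1. After quantile normalization Snap25 differed by -0.042 in place of -0.35, Cpe by -0.018 in place of -0.35 and Glul by -0.18 in place of -0.39. Rasl11b, Pdlim7, Dock3 and Mis18a were dimmer, and after quantile normalization they differed by -0.44, -0.68, -0.58 and -1.16.

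**Figure D1:**
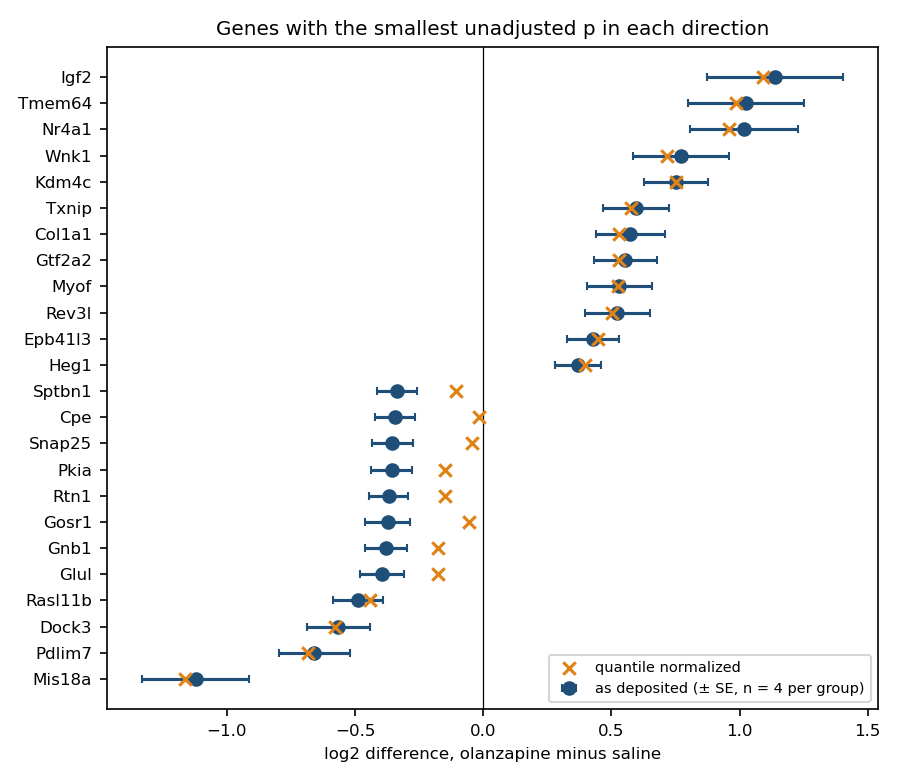
Log2 difference between olanzapine and saline for the 24 named genes, as deposited (circles, bars show the standard error, n = 4 per group) and after quantile normalization (crosses). The 12 higher genes keep differences of 0.40 to 1.09 after quantile normalization, whereas the 8 brightest lower genes move to between -0.18 and -0.018.

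Meningeal transcripts were the list with the smallest p. Ptgds, the prostaglandin D synthase gene, differed by 0.80 (SE 0.28), Col1a2 by 0.73 (SE 0.25), Col3a1 by 0.52 (SE 0.22) and Igf2 by 1.14 (SE 0.26). Of the 10 members measured, 0 passed over all probe sets and 4 passed when adjusted over the list alone. Camera gave an adjusted p of 2.38e-06 at the preset correlation. With an estimated correlation the camera p was 0.0315 before adjustment and 0.693 after adjustment over the 24 lists. List means were 8.33 ± 0.07 in saline and 8.86 ± 0.35 in olanzapine (SD, n = 4), with every olanzapine array above every saline array (exact permutation p = 0.0286, adjusted over the 24 lists 0.686). The highest array was olanzapine 9 at 9.36, and without it the list's median was 0.38 and Col1a2 differed by 0.45.

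Activity-regulated genes, which neurons induce within minutes to hours of firing, had 17 of 25 measured members higher in olanzapine and a median difference of 0.21. Beside Nr4a1, Homer1 differed by 0.60 (SE 0.21), Fosb by 0.55 (SE 0.21), Klf10 by 0.46 (SE 0.17) and Nr4a3 by 0.44 (SE 0.19). Egr4 differed by -0.35 (SE 0.19) and Bdnf by -0.21 (SE 0.17). Saline 19 was low in Fosb, at 9.40 against 9.78 to 10.71 in the other saline arrays, and in Nr4a3, at 10.10 against 10.66 to 11.43. Saline 14 was high in Egr4, at 9.41 against 8.71 to 9.26, and in Bdnf, at 8.97 against 8.43 to 8.80. These single arrays bear on those differences. Across all probe sets 0 members passed, and 1 did when adjusted over the list alone. The camera adjusted p was 0.0372 at the preset correlation and the adjusted p was 0.788 with an estimated correlation. Without saline 17 the median was 0.040, and without saline 19 it was 0.034, with camera adjusted p-values of 0.669 and 0.374, and Homer1 differed by 0.33 without saline 19. The call was also lost without olanzapine 18 (adjusted p = 0.169) and without olanzapine 19 (adjusted p = 0.220). By the limit given below for a moved value, the median moved only without saline 17 and without saline 19. The calls lost without olanzapine 18 and olanzapine 19 therefore need not be lost shifts.

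Genes responsive to glucocorticoids were higher in olanzapine in 12 of 13 measured members, with a median of 0.15. Cdkn1a, a cell cycle inhibitor gene, differed by 0.70 (SE 0.27), the clock gene Per1 by 0.53 (SE 0.26) and the repressor gene Bcl6 by 0.22 (SE 0.11), and Per1 also belongs to the activity-regulated list. Cdkn1a differed by 0.40 without saline 17, Per1 by 0.33 without saline 15 and Bcl6 by 0.14 without saline 19. Fkbp5, a co-chaperone of the glucocorticoid receptor, differed by 0.12 (SE 0.14). No member passed, over all probe sets or when adjusted over the list alone. The camera adjusted p was 0.00839 at the preset correlation and the adjusted p was 0.693 with an estimated correlation. At the preset correlation it was 0.0576 without saline 17 and 0.0586 without saline 19, where the median was 0.19 in both, and 0.231 without olanzapine 18, where it was 0.096.

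In oxidative phosphorylation, a part of energy metabolism, 39 of 51 measured members were lower and 12 higher, with a median of -0.086. Lower ones included the cytochrome oxidase subunit genes Cox7b at -0.30 (SE 0.08) and Cox6c at -0.27 (SE 0.08) and the ATP synthase subunit gene Atp5f1e at -0.25 (SE 0.08), and Uqcrfs1 of complex III was higher by 0.21 (SE 0.10). In glycolysis 15 of 18 were lower, with a median of -0.095, among them Tpi1 at -0.34 (SE 0.09), Pgk1 at -0.22 (SE 0.09) and Ldhb at -0.27 (SE 0.11), which was -0.17 without olanzapine 19. Over all probe sets 0 members of either list passed, and adjusted over the list alone 0 and 1 did. Camera gave adjusted p-values of 0.000346 and 0.0021 at the preset correlation, and with an estimated correlation the adjusted p was 0.693 for both. After quantile normalization these were 0.0904 and 0.442. Without saline 15, the array with the highest mean of both lists, they were 0.0515 and 0.194, with medians of -0.032 and -0.024. Both calls were kept with each other array left out, with a median of -0.057 for oxidative phosphorylation without olanzapine 19 and of -0.18 for glycolysis without saline 19.

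Astrocyte markers were lower in 9 of 14 measured members, with a median of -0.083. The glutamate transporter gene Slc1a3 differed by -0.30 (SE 0.08), and the gap junction gene Gja1 by -0.22 (SE 0.08) as deposited but by 0.080 after quantile normalization and 0.0062 after cyclic loess. Of the list, 0 members passed over all probe sets and 2 when adjusted over the list alone. Presynaptic vesicle genes were lower in 12 of 17 measured members, with a median of -0.11 that turned to 0.012 after quantile normalization. Sv2b differed by -0.35 (SE 0.09) and Nsf by -0.29 (SE 0.12). In contrast Vamp2 differed by 0.82 (SE 0.36), with an SD of 0.34 in saline and 1.06 in olanzapine. The mean over the list was -0.019. Here too 0 members passed over all probe sets and 2 when adjusted over the list alone. Camera gave adjusted p-values of 0.0244 for astrocyte and 0.0361 for presynaptic genes, and with an estimated correlation the adjusted p was 0.693 for both. After quantile normalization the astrocyte adjusted p was 0.733. It was 0.0590 without saline 15 (median -0.11), 0.0933 without saline 17 (-0.093) and 0.303 without olanzapine 19 (-0.020), and the call was kept without saline 19 (-0.039) and olanzapine 14 (-0.15). The presynaptic adjusted p was 0.106, 0.135 and 0.105 without saline 14, 15 and 17 (medians -0.12, -0.065 and -0.079), and 0.176 and 0.0726 without olanzapine 14 and 18 (-0.13 and -0.16). Without saline 19 its call was kept, with a median of -0.21.

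**Figure D2:**
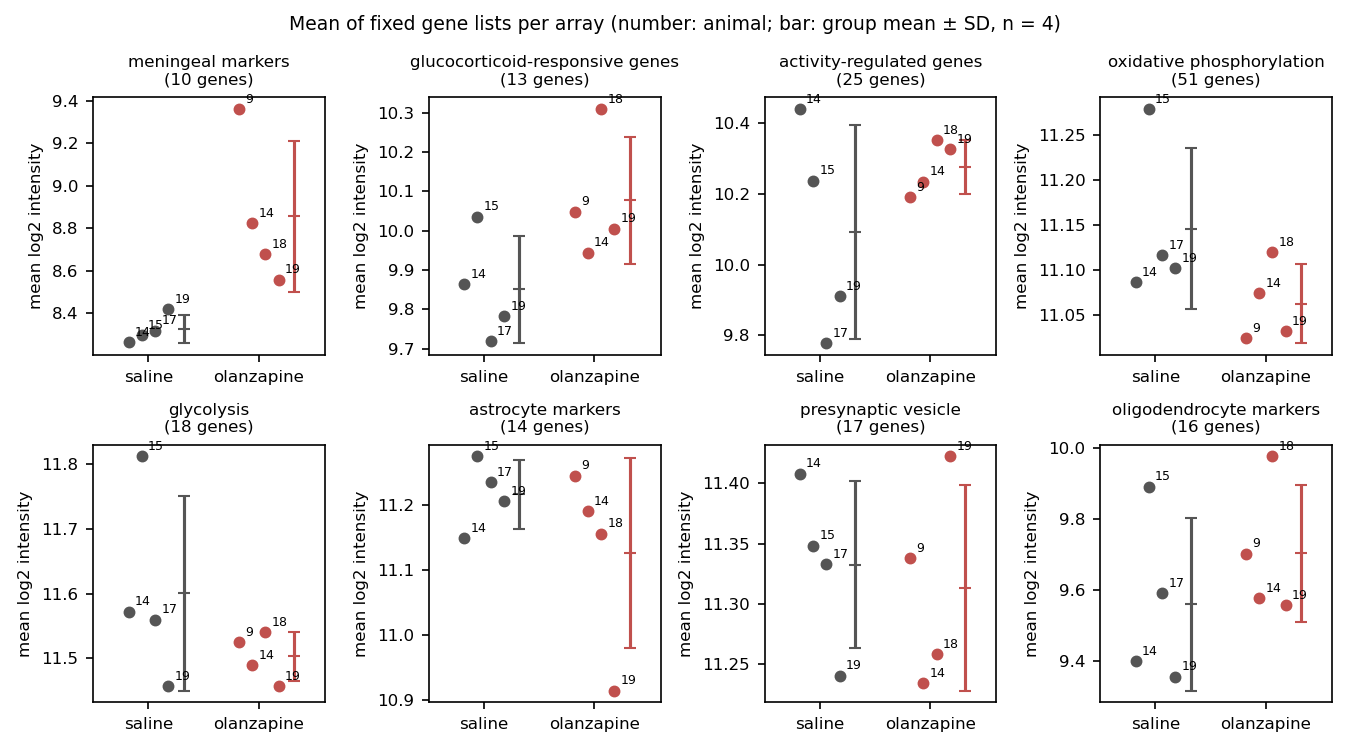
Mean log2 intensity of 8 gene lists on each array (points, labelled by animal number), with the group mean and SD (n = 4) as bars. All 4 olanzapine arrays lie above the saline arrays for meningeal markers, from 8.56 to 9.36 against 8.27 to 8.42, while the groups overlap for the other 7 lists.

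The spike-in control RNAs, which are added during preparation and do not come from the animals, were at a mean log2 intensity of 13.16 ± 0.22 in saline and 12.57 ± 0.27 in olanzapine (SD, n = 4, exact permutation p = 0.0571, 9 probe sets). The intensity at the 98th percentile was 6127 to 6204 in saline 14, 15 and 17, 5567 in saline 19 and 5451 to 5692 in olanzapine. The brightest 5% of tested probe sets had a median log2 difference of -0.15 as deposited and 0.00076 after quantile normalization. Cox7b, Cox6c, Atp5f1e, Pgk1, Slc1a3, Sv2b, Scd2, Hsph1, Gria3 and Gria2 also lay there, and the differences given for them are as deposited. The 4 called lists with lower values in olanzapine, those of oxidative phosphorylation, glycolysis, astrocytes and presynaptic vesicles, were not called after quantile normalization, with medians of -0.043, -0.041, -0.027 and 0.012. Among random lists matched on expression, glycolysis, astrocyte and presynaptic genes lay at percentiles 24.05, 40.6 and 26.1, whereas oxidative phosphorylation lay at 2.69, with a matched median of -0.041.

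**Figure D3:**
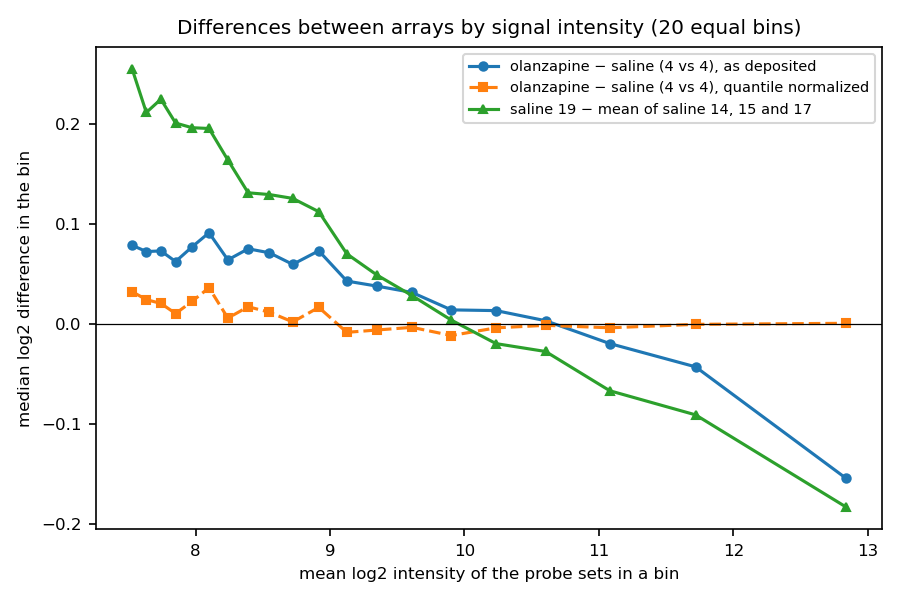
Median log2 difference in 20 equal bins of probe sets by mean log2 intensity. Olanzapine against saline runs from 0.078 in the dimmest bin to -0.15 in the brightest as deposited and stays between -0.012 and 0.036 after quantile normalization, and saline 19 against the mean of the other saline arrays runs from 0.25 to -0.18.

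None of the genes fixed by name passed. Reln, the gene of the extracellular protein reelin, differed by 0.027 (SE 0.12), with the sign turned to -0.025 by median centring. The serotonin receptor gene Htr2a differed by 0.12 (SE 0.19), the kinase gene Gsk3b by 0.15 (SE 0.30) and the signalling regulator gene Rgs2 by 0.056 (SE 0.11). Gad1, which encodes an enzyme that makes the transmitter GABA, differed by -0.023 (SE 0.09) as deposited and by 0.11 after both quantile normalization and cyclic loess. Homer1, a postsynaptic scaffold gene, had a limma adjusted p of 0.480. With 1 array left out at a time Reln ran from -0.042 to 0.11, Htr2a from -0.015 to 0.23, Gsk3b from -0.15 to 0.35, Rgs2 from 0.022 to 0.11 and Gad1 from -0.089 to 0.033.

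Of 21 genes of receptors that olanzapine binds, all on the array, only 10 were left by the filter on dim probe sets. Of these 10, 8 were lower, with a median of -0.13 and a camera adjusted p of 0.349. The median was -0.053 without saline 14, -0.074 without saline 15 and -0.19 without olanzapine 18. The muscarinic receptor gene Chrm3 differed by 0.32 (SE 0.17), the serotonin receptor gene Htr7 by -0.27 (SE 0.19) and the histamine receptor gene Hrh1 by -0.32 (SE 0.23), which was -0.15 without olanzapine 14. Median differences were 0.016 for sterol synthesis (camera adjusted p = 0.962) and -0.044 for fatty acid synthesis (0.541), where Scd2 differed by -0.27 (SE 0.09) and Acss2 by 0.27 (SE 0.12). Reelin pathway genes had a median of 0.020 (0.703) and Akt, GSK3 and Wnt signalling genes one of -0.086 (0.235). Without olanzapine 9 camera called the latter (median -0.11, adjusted p = 0.0237), with an adjusted p of 0.425 at an estimated correlation, and without olanzapine 14 and 18 its medians were -0.041 and -0.029 and it was not called. In this list Ctnnb1, the beta-catenin gene, differed by -0.30 (SE 0.09) as deposited and by 0.023 after quantile normalization. The list also held Pdk1, which encodes a pyruvate dehydrogenase kinase, and was not tested without that gene. Genes that handle catecholamines and serotonin had a median of 0.074 (0.537), and genes of heat shock and ER stress one of 0.059 (0.703), with the chaperone genes Calr at 0.23 (SE 0.08) and Hsph1 at -0.31 (SE 0.12). With 1 array left out these 2 medians ran from 0.040 without saline 14 to 0.15 without saline 19, and from 0.0017 without olanzapine 18 to 0.11 without saline 14.

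Synaptic receptor groups and neuron markers were not called. Glutamate receptor genes had a median of 0.023 (camera adjusted p = 0.842) that turned to -0.016 after quantile normalization. As deposited, the AMPA receptor genes Gria3 and Gria2 differed by -0.34 (SE 0.09) and -0.23 (SE 0.08). Both genes lay among the brightest 5% of probe sets, whose median difference was -0.15 as deposited and 0.00076 after quantile normalization. GABA-A receptor subunit genes had a median of -0.10 (0.537) and postsynaptic scaffold and kinase genes one of -0.070 (0.212), which turned to 0.037 after quantile normalization. With 1 array left out the GABA-A median ran from -0.13 without olanzapine 19 to -0.046 without saline 14, and the postsynaptic one from -0.091 without saline 14 to -0.022 without olanzapine 19. Markers of GABAergic interneurons had a median of 0.042 (0.962), markers of excitatory neurons one of -0.041 (0.944) and markers of striatal medium spiny neurons one of -0.045 (0.988).

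Markers of the remaining cell types were not called by the model without covariates at equal array weights. Oligodendrocyte markers were higher in 13 of 16 measured members, with a median of 0.16 (camera adjusted p = 0.138) and the myelin gene Mobp at 0.51 (SE 0.24), which was 0.33 without olanzapine 18 and 0.79 without saline 15. Camera called them with array weights (adjusted p = 0.0317), without saline 15 (0.00101), without olanzapine 14 (0.0285) and without olanzapine 19 (0.0423), and with an estimated correlation the adjusted p in these settings was 0.582 to 0.770. Without saline 14, saline 19 and olanzapine 18 the medians were 0.080, 0.082 and 0.060, with adjusted p-values of 0.481, 0.672 and 0.901 at the preset correlation. Microglia markers had a median of 0.060 (0.282), with 7 of 10 measured members higher and 3 lower. Among them Trem2, a microglial receptor gene, was at 0.77 (SE 0.29) and Cd74 at 0.46 (SE 0.20). Trem2 differed by 0.40 without saline 17 and Cd74 by 0.29 without olanzapine 9, and the list's median ran from 0.024 without olanzapine 9 to 0.14 without olanzapine 19. Endothelial and pericyte markers had a median of 0.042 (0.756), which turned to -0.0029 after quantile normalization. Of 14 measured members 8 were higher and 6 lower. Pecam1 differed by 0.38 (SE 0.11), Ocln by 0.50 (SE 0.20) and Kdr by -0.29 (SE 0.14), which was -0.18 without olanzapine 19. Blood cell markers had a median of 0.086 over 3 genes (0.647).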

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

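Within each group of 4 arrays, an array was singled out when its gap to the nearest other array took more of the group's range than the critical value of Dixon's test for 4 values, which chance does in about 1 of 20 groups. Of 252 groups tested, 19 had such an array, 7.54%, of which 8 were in saline 19 and 5 in olanzapine 9. The test of signal compression described next was chosen after the result was seen.

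In saline 19, bright genes stood below the other saline arrays in log2 intensity. Ctnnb1 was at 14.16 against 14.48 to 14.50, Gosr1 at 14.20 against 14.47 to 14.52, Gja1 at 14.18 against 14.39 to 14.44, Sptbn1 at 13.70 against 13.90 to 13.93, Pkia at 13.39 against 13.56 to 13.58 and the AMPA receptor gene Gria2 at 13.33 against 13.57 to 13.61. Its 98th percentile of intensity was 5567 against 6127 to 6204, and its mean over the brightest 5% of all probe sets was 12.38 against 12.52 to 12.53. The ratio of 3' to 5' probe sets of the actin control, which rises as RNA degrades, was 29.4 in saline 19. It was 7.74 to 16.7 in the other saline arrays and 9.18 to 20.6 in olanzapine. The GAPDH ratio of saline 19 was 4.55, against 4.79 to 5.99 in the other saline arrays and 3.62 to 5.80 in olanzapine. Both ratios were thus 3.62 or higher on every array, so the RNA of the other arrays cannot be taken as intact.

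Bright probe sets were lower in olanzapine, and saline 19 resembled the olanzapine arrays in this. Against a loss of neuronal transcripts as the source, 42 presynaptic, postsynaptic and excitatory neuron genes had a median at percentile 38.9 of lists matched on expression, which neither sets them apart nor excludes it. If the signal of individual arrays was compressed, which may happen in hybridisation or scanning, spike-in controls and bright probe sets should deviate together within groups. Over the 8 arrays r was 0.507 (one-sided permutation p = 0.161) and rho was 0.452 (one-sided permutation p = 0.156). Without olanzapine 9 and saline 19, the arrays farthest from the median, r was 0.526. Those deviations were still taken from the means of all 4 arrays of a group. That value therefore also holds a difference between groups, and cannot show whether the within-group r depends on these arrays. Neither a loss of neuronal transcripts nor compression is settled by these values. Compression and treatment cannot be told apart with 4 arrays a group, and no array batch was given in the sources used here. The split of saline 14, 15 and 17 with olanzapine 18, the arrays with the highest 98th percentiles, from the rest gave 1820 probe sets at an unadjusted p under 0.05, more than the 1549 between the treatments.

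Olanzapine 9 stood apart in Igf2 at 9.45 against 8.30 to 8.42, in the tight junction gene Ocln at 8.91 against 8.37 to 8.46, and in the mean of genes handling catecholamines and serotonin at 8.98 against 8.82. It was low in Klf10 at 10.71 against 11.27 to 11.32 and in Acss2, an acetyl-CoA synthetase gene, at 10.96 against 11.39 to 11.47. Olanzapine 14 was low in Epb41l3 at 11.27 against 11.50 to 11.53. Saline 17 was low in Nr4a1 at 7.33 against 8.19 to 8.34 and in the phosphodiesterase gene Pde1b at 10.10 against 10.53 to 10.59. Saline 14 was high in Rgs2 at 9.91 against 9.68 to 9.70 and in the mean of striatal medium spiny neuron markers at 9.31 against 9.22 to 9.23. Saline 15 was high in the mean of oxidative phosphorylation genes at 11.28 against 11.09 to 11.12.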

How the results depend on the processing

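Cyclic loess and saline 19 alone against olanzapine were chosen after seeing the data. Of the results for 96 named probe sets, 84 kept their sign in every setting run, and so did 8 of 24 lists; the cause of the changes below was not tested unless stated. The meningeal list stayed called in every setting with a list test except the estimated correlation and fry, where the median was the same 0.49; with arrays left out its median was 0.38 to 0.59. Probe sets past the adjusted test numbered 6 with the replicate block, and 0 to 107 with 1 array left out, the 107 without saline 19, with 12 of the 24 named genes and Ctnnb1, Slc1a3, Scd2, Gria3, Cox7b and Sv2b among them, and 1 without olanzapine 9; under quantile normalization without saline 19 it was 5. Counts at an unadjusted p under 0.05 were 991 with the block and 1154 to 2151 with an array left out. With a 1.5-fold difference as well, counts were 427 with 1 added before the log and 54 with the pooled median added, which by construction widens and narrows log2 differences; 630 with no filter and 90 with the 60th percentile filter, where more and fewer probe sets were tested; 108 with the plain two-sample test, 498 with the block and 216 to 481 with an array left out, the 481 without saline 19. Lists called numbered 3 under quantile normalization, 4 without a trend in eBayes, 3 with the block, 0 with the estimated correlation, 0 with fry, 3 under cyclic loess, and 3 to 8 with an array left out, 4 without saline 15, 3 without saline 17 and 4 without olanzapine 18. The activity-regulated list also lost its call with 1 added before the log (adjusted p 0.0777), with no filter (0.106), without a trend (0.135) and with all probe sets of each gene (0.121), and the presynaptic list with median centring (0.117), no filter (0.0725), no trend (0.148), all probe sets of each gene (0.165), cyclic loess (0.729) and the block (0.853), and without saline 14 (0.106), saline 15 (0.135), saline 17 (0.105), olanzapine 14 (0.176) or olanzapine 18 (0.0726). The astrocyte list lost its call without a trend (0.0751), under cyclic loess (0.521), with the block (0.222), and without saline 15 (0.0590), saline 17 (0.0933) or olanzapine 19 (0.303). Oxidative phosphorylation lost it under cyclic loess (0.145) and with the block (0.351), and glycolysis under cyclic loess (0.409) and the block (0.351). The activity-regulated (0.351) and glucocorticoid (0.247) lists lost it with the block. The trend in eBayes does not enter the medians, so the calls lost without it left the medians unchanged. In the other settings too, a lost call need not be a lost shift. The oligodendrocyte list became called with array weights (0.0317) and the block (0.0173), and without saline 15 (0.00101), olanzapine 14 (0.0285) or olanzapine 19 (0.0423), and the Akt, GSK3 and Wnt list with the block (median -0.14, 0.0173) and without olanzapine 9 (-0.11, 0.0237). With an estimated correlation the adjusted p in these settings was 0.582 to 0.976 for the first and 0.976 and 0.425 for the second. Signs turned under quantile normalization for Gad1 (0.11), Ctnnb1 (0.023), Gja1 (0.080), Shank1 (0.040) and the endothelial and pericyte (-0.0029), excitatory neuron (0.044), fatty acid (0.026), glutamate receptor (-0.016), postsynaptic (0.037) and presynaptic (0.012) lists. Median centring turned Reln (-0.025) and the endothelial and pericyte (-0.010), GABAergic interneuron (-0.010), glutamate receptor (-0.029), reelin (-0.032) and sterol (-0.036) lists. The 60th percentile filter turned the glutamate receptor (-0.0058) and reelin (-0.013) lists, and array weights Hbb (0.097). Cyclic loess turned Gad1 (0.11), Gja1 (0.0062), Hbb (0.011), Shank1 (0.011) and the endothelial and pericyte (-0.012), excitatory neuron (0.059), glutamate receptor (-0.022), heat shock (-0.0062) and postsynaptic (0.023) lists. Saline 19 alone is 1 array whose spread was borrowed from olanzapine, so its counts (7 probe sets past the adjusted test, 658 with a 1.5-fold difference, 4 lists called) may reflect that 1 animal and support no call; the comparison turned Gsk3b (-0.22), Htr2a (-0.21), Gad1 (0.17), Alas2 (-0.56), Maoa (-0.11), Gabrb2 (0.030), Crkl (-0.14) and the blood cell (-0.49), catecholamine and serotonin (-0.056), endothelial and pericyte (-0.022), excitatory neuron (0.075), fatty acid (0.055), GABA-A (0.095), glutamate receptor (-0.0059), glycolysis (0.015) and presynaptic (0.0059) lists. The animal numbers 14 and 19 occur in both groups but nothing states that they pair animals, and deviations of same-numbered arrays correlated at 0.0746 and 0.109; the replicate block left 1 residual degree of freedom and turned Gsk3b (-0.20), Alas2 (-0.29) and the blood cell (-0.054), endothelial and pericyte (-0.026), excitatory neuron (0.017), GABAergic interneuron (-0.017), heat shock (-0.024), microglia (-0.0075), postsynaptic (0.015) and striatal (0.045) lists. The 24 named genes were chosen because their groups lay apart on these same arrays, so their count with arrays left out shows no robustness. Leaving out 1 array at a time turned the sign, or moved the value by over 1.5 times, for 40 of the 96 named probe sets. It did so for 0 of those 24 genes and for 23 of 24 lists, all but the meningeal one. It gave both signs for Alas2 (-0.073 to 0.30), Gad1 (-0.089 to 0.033), Gsk3b (-0.15 to 0.35), Hbb (-0.27 to 0.16), Htr2a (-0.015 to 0.23), Maoa (-0.013 to 0.14), Reln (-0.042 to 0.11) and the blood cell (-0.073 to 0.30), endothelial and pericyte (-0.049 to 0.096), excitatory neuron (-0.081 to 0.019), fatty acid (-0.11 to 0.020), GABAergic interneuron (-0.0058 to 0.072), glutamate receptor (-0.027 to 0.079), reelin (-0.030 to 0.071), sterol (-0.033 to 0.061) and striatal (-0.056 to 0.051) lists. List tests were not run for robust eBayes and the plain test. Detection calls were not used here, so how far dim probe sets stood above background is unknown.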

Other observations

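The split of the arrays by treatment was set against all 35 splits of the 8 arrays into 4 and 4, a test fixed before the data were examined except for the count of adjusted calls. Of the tests in this part, those chosen only after the result was seen were that count, the vessel criterion and the coordination of activity-regulated genes.

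Choroid plexus transcripts, a possible carry-over from the ventricles, were mostly too dim to test. Ttr, the most abundant transcript of that tissue, was at a log2 intensity of 7.54 ± 0.22 in saline and 7.20 ± 0.62 in olanzapine (SD, n = 4), and only Kcnj13 and Sostdc1 were kept by the filter, with differences of 0.29 and 0.58. The percentile of the oligodendrocyte list's median among 10000 lists matched on expression was 99.7. Receptors that olanzapine binds were at 0.990, oxidative phosphorylation at 2.69, glycolysis at 24.05, presynaptic vesicle genes at 26.1 and astrocyte markers at 40.6. The meningeal and activity-regulated lists were at 100 and the glucocorticoid list at 99.4. Random lists do not hold the correlation between members of a list, so these percentiles are not p-values.

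Of the 35 splits, 2 gave at least the 1549 probe sets at an unadjusted p under 0.05 found between the treatments, the highest other being 1820. For the 227 that also differed 1.5-fold it was 5 splits, the highest other being 370, and for the 7 lists called by camera it was 6 splits, the highest other being 8. Chance was therefore excluded for none of these 3 counts. The median of the other splits was 3 called lists, although simulated lists without a shift, in noise independent between probe sets, gave 0 calls in 240 tests. The 0 adjusted calls between the treatments could not be tested this way, since all 35 splits give at least 0, the highest other being 3.

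Meningeal transcripts were higher in olanzapine, and 1 hypothesis is that the dissections of these animals held more meningeal tissue. Without Igf2 and Col1a1, already seen among the named genes, all 8 other members were higher with a median of 0.42, and their list mean had an exact permutation p of 0.0571, which leaves this open. For a larger share of vessels, the mean of the endothelial and pericyte list differed by 0.048 (exact permutation p = 0.571). Its median lay below the meningeal one by more than the SD of its members, 0.24. That criterion was written after the vessel result had been seen, and its SD is between genes, not between animals. By the criterion written first, a difference at or below 0, the result was undecided, so a larger share of vessels is not excluded. An effect of olanzapine on meningeal or perivascular fibroblasts was not tested and stays open.

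Activity-regulated genes varied more among saline than among olanzapine animals, with list means of SD 0.30 and 0.076 (n = 4 each), a difference that was not tested. After removing group means, the 25 members correlated over the 8 arrays at a mean pairwise r of 0.302, against 0.00059 in lists matched on expression, percentile 100. This correlation restates the spread, since a list mean spreads widely only where its members go together, so it does not separate animal from technical sources. Saline 17 and 19 had the lowest list means, 9.78 and 9.91, and the call of this list was lost without either of them.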
